A study of Danio rerio with 12 samples.

How the data were processed

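Total RNA sequencing was carried out on whole zebrafish embryos collected at 12 hours post fertilisation. The 12 libraries formed 4 groups of 3: wild type with DMSO, wild type with 5-aza-2'-deoxycytidine (5AzadC, a cytosine analogue that blocks DNA methyltransferases), H2A.Z-mCherry with DMSO, and H2A.Z-mCherry with 5AzadC. H2A.Z-mCherry is a line that carries the histone variant H2A.Z fused to a red fluorescent protein. Per the labels, fertilised eggs were held at about 50 per well in 5 mL and received 100 µM 5AzadC or 0.1% DMSO from just after spawning. The labels give AB/Tuebingen as the wild-type stock. They do not say whether the replicates came from separate clutches, wells or days, so the p-values below measure the spread between these libraries. Other assays, stages and compounds that the series title and design mention were not used here.

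The authors deposited a table of raw read counts for each Ensembl gene in each library, with the replicates kept apart and no normalization. The submitters' notes name STAR, featureCounts 2.0.3 from Subread, DESeq2 1.22.2, deepTools and the genome build GRCz11, without the role or order of each tool. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads shared between close paralogs are therefore counted in an unknown way, and values of paralog pairs such as h2az2b and H2AZ2 are uncertain to that extent. Whether reads of the H2A.Z-mCherry transgene count towards an endogenous H2A.Z gene is not given in the sources used here either, so levels of these genes in that line may hold transgene reads. The authors also deposited a DESeq2 table for 5AzadC against DMSO in each genotype. These tables give a mean normalised count signal over all 12 libraries, a log2 fold change with its standard error, a Wald score, and p-values with Benjamini-Hochberg adjusted values, all computed by the authors. The mean signal was the same in both deposited tables for all 32520 genes within a relative tolerance of 1e-06. It also equalled the 12-library mean of the normalised counts, so both tables rest on the same 12 libraries and scaling. Whether they came from a single fit was not tested. These tables were used only for a comparison of fold changes.

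The count table held 32520 genes, of which 29201 had a symbol and 7468 had no count in any library. Many symbols are written in the human style and some are shared by several zebrafish genes; identifiers are given where a symbol is shared. Library totals ran from 1142051 to 1904063 counts, so 1 count equalled 0.876 CPM (counts scaled to a fixed library total) in the smallest library and 0.525 CPM in the largest. Intervals and limits from counts cover counting error only. Where a group had no count for a gene, the fold is given as a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% interval from an exact binomial test.

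Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the filterByExpr function, which left 12293 genes with 98.5% of all counts. Libraries were scaled by the trimmed mean of M values (TMM). All 12 libraries entered a single quasi-likelihood fit with robust dispersion estimates and 1 coefficient per group. The common biological coefficient of variation was 14.8%. Of the 5 contrasts, a pair tested 5AzadC against DMSO within each genotype, another pair tested H2A.Z-mCherry against wild type within each treatment, and the last was the interaction, the response in H2A.Z-mCherry minus the response in wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12293 tested genes. Every adjusted p of a single gene is from this edgeR fit unless another tool is named. Errors of log2 fold changes (± without SD) are the absolute log2 fold change over the square root of the F statistic of its test. They rest on 3 libraries in each group and are approximate, since the fit does not estimate them. For most of the genes named below for 5AzadC against DMSO they are smaller than the standard errors in the authors' tables.

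The size of the response in H2A.Z-mCherry relative to wild type was measured by an orthogonal regression slope through the log2 fold changes of all tested genes, with a 95% interval from 1000 bootstrap draws over genes. Genes are not independent replicates, so this interval says nothing about the spread between embryos. The share of called genes with the smaller response in the other genotype was computed in both directions and set beside simulated counts with equal effects in both genotypes.

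The 22 gene lists covered H2A.Z genes, H2A.Z deposition and removal, the DNA methylation machinery, germline genes, the interferon response and nucleic acid sensing, p53 targets, apoptosis and stress response, DNA replication and cell cycle, early transcription factors of the blastula and gastrula, somite and presomitic mesoderm, skeletal muscle, notochord and axis, neural plate and neurons, hox genes, neural crest, blood and endothelium, heart and lateral plate mesoderm, endoderm, epidermis and periderm, hatching gland, yolk syncytial layer, and maternal oocyte transcripts. Of their 572 entries 552 matched a gene in the table, 116 of these through a human-style symbol, and the lists held 384 tested members. Such a symbol brought in every gene that carries it. These numbers are sums over lists, and some genes are in more than 1 list, such as PRDM1 in neural crest and hatching gland. Lists with at least 5 tested members went to camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, and p was adjusted over the 21 lists of a contrast. Camera compares a list with all other tested genes. Each test was repeated with a correlation estimated from the data. The fry test was run beside it, for movement in 1 direction and for change in either direction; it does not compare a list with other genes. Member counts are given over all tested genes and adjusted over the list alone.

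Genes named below follow a rule. For each contrast they are the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM in the higher group, a symbol that is not clone-based, and groups that do not overlap (no rule on overlap for the interaction). To these are added up to 4 called members of each list with the largest change, or the member with the smallest p where none passed, and every tested H2A.Z and DNA methyltransferase gene. The values of 1 gene that the rule names are not reported here, although counts of named genes include it. The contrasts, their tests, the lists, the naming rule and the alternatives named below, except those said to be later, were fixed before the data were examined; what was chosen later is named as such where it appears.

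The alternatives were DESeq2 size factors, upper quartile factors, scaling without the 20 most counted genes, no filter except genes without a count, a filter of at least 1 CPM in 3 libraries (looser than filterByExpr, with 19574 genes), a threshold of 0.01, an absolute log2 fold change of at least 1, a fit of the compared groups alone, the replicate number as a block, the DESeq2 1.42.0 Wald test, and each library left out in turn. Thinning of all libraries to the lowest total and a stricter filter of at least 20 CPM in 3 libraries were added after seeing the data. Other splits of the libraries were counted for each contrast. The pipeline was tested on simulated data with 200 changed genes. For 5AzadC against DMSO in wild type it called 86.4% of the simulated 4-fold changes, 61.2% of the 2-fold and 14.9% of the 1.5-fold changes, with 2 false calls among 110. For the interaction it called 66.7% of the 4-fold, 23.9% of the 2-fold and 2.99% of the 1.5-fold changes, with 5 false calls among 67. A test of genes on the long arm of chromosome 4 was planned and not run, since the reference annotation is of another build than the counts. For the same reason no gene positions or lengths are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.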

Results

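Gene expression was measured by total RNA sequencing in whole zebrafish embryos of 2 genotypes, wild type and H2A.Z-mCherry, each given DMSO or the DNA methylation inhibitor 5AzadC until 12 hours post fertilisation, with 3 libraries in each of the 4 groups. The mean total count per library was 1614284 ± 110014 (SD, n = 3) in wild type with DMSO and 1277001 ± 132126 (SD, n = 3) in wild type with 5AzadC. It was 1370248 ± 255283 (SD, n = 3) in H2A.Z-mCherry with DMSO and 1663950 ± 280703 (SD, n = 3) in H2A.Z-mCherry with 5AzadC. The share of counts from rn7sl1, the RNA of the signal recognition particle, was 9.22% ± 0.08, 9.75% ± 0.45, 8.02% ± 0.90 and 7.37% ± 1.15 (SD, n = 3) in the same order of groups. In the principal components of log2 CPM the 4 groups lay apart from each other, and PC1 held 29.3% and PC2 21.8% of the variance.

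**Figure D1:**
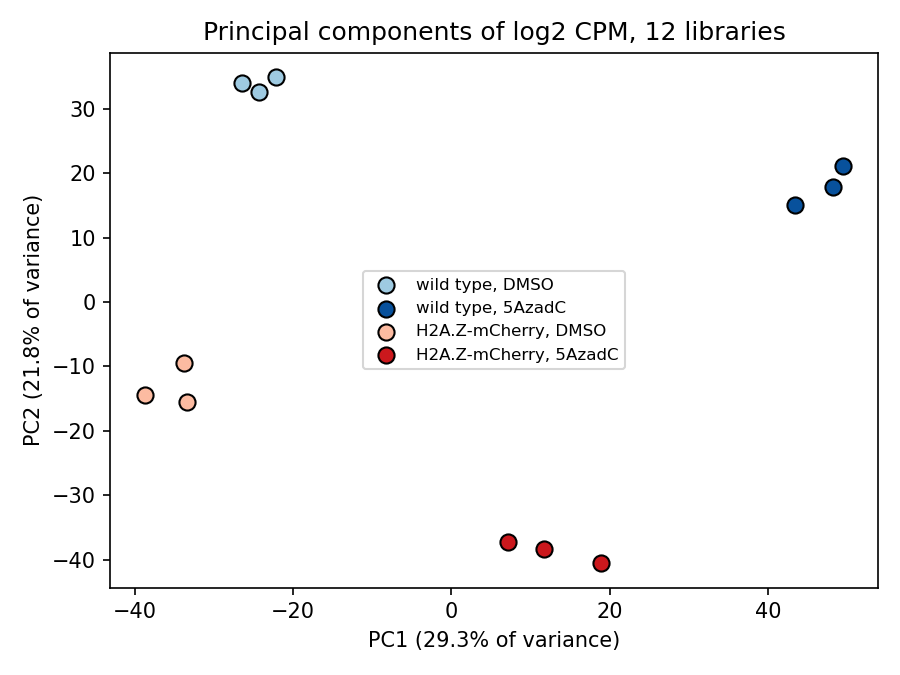
Principal components of the log2 CPM of tested genes, with PC1 (29.3% of the variance) on the x axis and PC2 (21.8%) on the y axis; each point is 1 of the 12 libraries, coloured by group. The 3 libraries of each group lie together and apart from the other 3 groups.

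The first comparison asked which genes 5AzadC changed in wild-type embryos. The H2A.Z list also held h2az1, which matched no gene in the table and was not tested. Both H2A.Z genes that matched the list were higher with the drug. The more abundant, h2az2b (ENSDARG00000116491), rose from 394 ± 34.2 to 694 ± 44.6 CPM (SD, n = 3), a log2 fold change of 0.82 ± 0.09 (SE) with an adjusted p of 1.46e-11. H2AZ2 (ENSDARG00000068820) rose from 44.9 ± 5.85 to 66.3 ± 7.16 CPM (SD, n = 3), with a log2 fold change of 0.57 ± 0.21 and an adjusted p of 0.0382. That call for H2AZ2 was lost with DESeq2 (adjusted p 0.075), with upper quartile factors (0.0505) and when any of 4 libraries was left out, with p as high as 0.149 without wild-type 5AzadC replicate 2. The other 3 libraries were wild-type DMSO replicates 1 (0.102) and 2 (0.139) and wild-type 5AzadC replicate 1 (0.0693). Both counts of the list were 2 of 2 when adjusted over the list alone.

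Genes of the p53 pathway, which halts the cell cycle and triggers cell death after DNA damage, had the highest median of the 21 tested lists in wild type. Of 22 tested p53 targets 18 rose, also 18 adjusted over the list alone, with a median log2 fold change of 2.60 (camera adjusted p 2.75e-46; adjusted p = 0.000294 with an estimated correlation). GADD45A, a DNA damage gene, rose by 5.09 ± 0.43 on the log2 scale (adjusted p 5.24e-14), and PHLDA3, an inhibitor of AKT signalling, rose by 4.50 ± 0.30 (adjusted p 1.43e-15). The cell death gene bbc3 rose by 3.95 ± 0.62 (adjusted p 0.00172) and foxo3b rose by 3.93 ± 0.34 (adjusted p 4.1e-05). In the list of apoptosis and stress response 9 of 18 genes rose, or 10 with 1 fall adjusted over the list alone (camera adjusted p 1.35e-09; adjusted p = 0.00644 with an estimated correlation). Its examples were the AP-1 transcription factor genes FOSL1 (2.37 ± 0.37, adjusted p 3.63e-07) and JUNB (ENSDARG00000104773, 2.09 ± 0.32, adjusted p 2.49e-07), and TXNIP (2.07 ± 0.10, adjusted p 4.63e-27), which binds thioredoxin. Of 9 interferon and nucleic acid sensing genes 4 rose, also 4 adjusted over the list alone (camera adjusted p 0.00111; adjusted p = 0.0256 with an estimated correlation). The ubiquitin-like gene isg15 had 238 counts with the drug against 2 without it, a ratio of 159 (95% interval 43.4 to 1320). For ifit8 the counts were 52 against 2, a ratio of 34.7 (9.13 to 294). The other calls, of IRF7 and adar, were lost with DESeq2 (adjusted p 0.0969 and 0.0816). The call of IRF7, whose groups overlapped, was also lost when any of 5 libraries was left out (up to 0.363). That of adar was lost without any of 4 libraries (up to 0.184).

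Genes of the outer covering of the embryo rose in wild type. Of 23 epidermis and periderm genes 18 rose, or 19 adjusted over the list alone, with a median of 0.90 (camera adjusted p 6.84e-18; adjusted p = 0.0146 with an estimated correlation). The tight junction gene cldnb rose from 29.4 ± 1.94 to 111 ± 28.9 CPM (SD, n = 3), by 1.91 ± 0.22 on the log2 scale (adjusted p 2.78e-10). The keratin gene krt8 rose by 1.37 ± 0.13 (adjusted p 1.88e-14) and ponzr5 rose by 1.34 ± 0.37 (adjusted p 0.00421). In the hatching gland list 4 of 6 genes rose, also 4 adjusted over the list alone, among them he1.1, a gene for a hatching enzyme (0.72 ± 0.17, adjusted p 0.000493), and XBP1 (0.50 ± 0.11, adjusted p 0.000281). That list passed with an adjusted p of 0.0399, but not with an estimated correlation (adjusted p = 0.24 with an estimated correlation), nor without wild-type DMSO replicate 1 (0.09), wild-type 5AzadC replicate 1 (0.0663) or replicate 2 (0.0703). In the yolk syncytial layer list, which holds lipoprotein genes, 8 of 22 rose and 2 fell, or 11 and 2 adjusted over the list alone (camera adjusted p 0.0102; adjusted p = 0.303 with an estimated correlation). MTTP, which loads lipid onto lipoproteins, rose by 0.83 ± 0.12 (adjusted p 6.66e-08) and apobb.2, an apolipoprotein B gene, fell by 1.23 ± 0.19 (adjusted p 2.79e-07).

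Genes of muscle and of the nervous system fell in wild type. Of 20 skeletal muscle genes 12 fell, or 14 adjusted over the list alone, with a median of -1.14 (camera adjusted p 3.02e-09; adjusted p = 0.00644 with an estimated correlation). The slow myosin gene smyhc2 fell by 3.16 ± 0.64 on the log2 scale (adjusted p 8.03e-05), the muscle transcription factor gene MEF2C (ENSDARG00000029764) fell by 2.48 ± 0.33 (adjusted p 2.92e-09) and the actin gene ACTA1 (ENSDARG00000055618) was 3.73-fold lower (adjusted p 0.000116). Of 35 neural plate and neuron genes 19 fell and 1 rose, or 24 and 1 adjusted over the list alone, with a median of -0.74 (camera adjusted p 8.88e-07; adjusted p = 0.00644 with an estimated correlation). PAX2 (ENSDARG00000032578), a transcription factor gene of the midbrain boundary, fell by 2.95 ± 0.48 (adjusted p 1.11e-06) and rx1, of the eye field, was 5.28-fold lower (adjusted p 0.000129). Of 31 hox genes, which pattern the body from head to tail, 9 fell, or 10 adjusted over the list alone (camera adjusted p 0.00255; adjusted p = 0.0277 with an estimated correlation). HOXD3 fell by 1.65 ± 0.26 (adjusted p 6.44e-07), and hoxa2b had 60 counts with DMSO against 3 with 5AzadC, a ratio of 15 (95% interval 4.89 to 74.8).

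Genes that copy DNA and its methylation were lower in wild type with 5AzadC. Of 12 DNA methylation genes 8 fell, also 8 adjusted over the list alone, with a median of -0.89 (camera adjusted p 6.97e-06; adjusted p = 0.0207 with an estimated correlation). DNMT1, the maintenance methyltransferase, fell from 298 ± 2.76 to 164 ± 21.2 CPM (SD, n = 3), by 0.86 ± 0.12 on the log2 scale (adjusted p 5.48e-09). Its partner UHRF1 fell by 1.05 ± 0.12 (adjusted p 3.47e-11), tet3, which oxidises methylcytosine, was 2.15-fold lower (adjusted p 1.51e-15), and DNMT3A (ENSDARG00000005394) fell by 1.75 ± 0.44 (adjusted p 0.00142). Another gene named DNMT3A (ENSDARG00000015566) was at -0.33 in the authors' table and did not pass there (DESeq2 adjusted p 0.633). Of 25 DNA replication and cell cycle genes 12 fell and 1 rose, also 12 and 1 adjusted over the list alone (camera adjusted p 0.000233; adjusted p = 0.0349 with an estimated correlation). The helicase gene MCM2 was 2.32-fold lower (adjusted p 2.95e-16), CCNE2, a cyclin of DNA replication, fell by 1.03 ± 0.20 (adjusted p 4.85e-05), and the mitotic cyclin gene CCNB1 rose by 0.89 ± 0.13 (adjusted p 2.76e-08).

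The remaining lists did not pass in wild type with camera. Early transcription factors of the blastula and gastrula had 6 rises and 2 falls among 22 (adjusted p 0.159), with foxi1 at 2.43 ± 0.33 (adjusted p 8.58e-09). Notochord and axis genes had 1 rise and 5 falls among 18, or 1 and 6 adjusted over the list alone (0.0932), with FOXA1 at -2.77 ± 0.45 (adjusted p 1.07e-06). Blood and endothelium genes had 4 rises among 15, or 5 adjusted over the list alone (0.104), with CEBPB at 1.46 ± 0.30 (adjusted p 7.69e-05). Heart and lateral plate mesoderm had 2 rises and 4 falls among 18, or 2 and 5 adjusted over the list alone (0.405). Neural crest had 3 rises and 4 falls among 18, or 5 and 4 adjusted over the list alone (0.607). Somite and presomitic mesoderm had 4 rises and 2 falls among 28 (0.607), endoderm 1 rise and 1 fall among 8 (0.607). H2A.Z deposition and removal had 2 rises and 1 fall among 14 (0.779). For these and the early transcription factors the counts were the same adjusted over the list alone. In the H2A.Z deposition list BRD2, whose protein reads acetylated histones, rose by 0.63 ± 0.10 (adjusted p 4.13e-07). Of 9 germline genes 1 passed over all genes (0.279), and the 9 tested maternal oocyte transcripts had a median of 0.09 (0.878). The test, median and mean did not share a sign for the somite, H2A.Z deposition and maternal lists.

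In all, 2745 of 12293 tested genes changed in wild type, 1312 higher and 1433 lower, of which 1213 changed by at least 1 on the log2 scale. Among the largest rises were rpz5, with 62 counts against 0, at least 27.6-fold higher, and EXO5, a single-strand exonuclease gene, at 4.38 ± 0.42 (adjusted p 2.34e-14). Among the largest falls was IGFBP3, a binding protein of insulin-like growth factors, with 0 counts against 38, at least 9.5-fold lower. The semaphorin receptor gene plxnb2b had 81 counts with DMSO against 1 with 5AzadC, a ratio of 60.8 (95% interval 10.6 to 2430). Of the 88 genes named by the rule that passed, 82 had no overlap between the libraries of both groups. These genes had passed the test, and the largest rises and falls were chosen for it. Over all tested genes the share was 35.2%, where chance gives 10%.

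The second comparison asked the same of H2A.Z-mCherry embryos, and here too both tested H2A.Z genes rose. For h2az2b the rise was from 473 ± 32.1 to 758 ± 80.04 CPM (SD, n = 3), a log2 fold change of 0.68 ± 0.09 (adjusted p 1.05e-08). For H2AZ2 it was from 41.7 ± 9.77 to 71.7 ± 8.69 CPM (SD, n = 3), a log2 fold change of 0.77 ± 0.21 (adjusted p 0.00456). Both passed adjusted over the list alone. In this line the levels of both genes may include reads of the transgene. Of 22 p53 targets 17 rose, also 17 adjusted over the list alone, with a median of 2.01 (camera adjusted p 7.51e-34; adjusted p = 0.0023 with an estimated correlation). GADD45A rose by 3.93 ± 0.48 on the log2 scale (adjusted p 9.63e-09), PHLDA3 by 3.90 ± 0.32 (adjusted p 2.23e-12) and rps27l, a ribosomal protein gene that p53 activates, by 3.25 ± 0.24 (adjusted p 3.56e-19). Of 23 epidermis and periderm genes 10 rose, or 11 adjusted over the list alone (camera adjusted p 0.000305; adjusted p = 0.296 with an estimated correlation). The annexin gene anxa1b rose by 1.08 ± 0.17 (adjusted p 7.33e-07) and the claudin gene cldna by 1.51 ± 0.36 (adjusted p 0.00122).

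Muscle, neural and hox genes fell in H2A.Z-mCherry as lists under the preset correlation. Of 20 skeletal muscle genes 4 fell, also 4 adjusted over the list alone (camera adjusted p 0.00753; adjusted p = 0.201 with an estimated correlation). Among them were both genes named TTN, for the giant sarcomere protein, at -0.82 ± 0.08 (ENSDARG00000028213, adjusted p 3.17e-13) and -0.74 ± 0.08 (ENSDARG00000000563, adjusted p 1.42e-10). Of 35 neural plate and neuron genes 10 fell and 1 rose, or 13 and 1 adjusted over the list alone (camera adjusted p 0.00288; adjusted p = 0.0897 with an estimated correlation). PAX2 (ENSDARG00000032578) was at -2.28 ± 0.45 (adjusted p 6.97e-05) and PAX6, a gene of eye and forebrain, at -1.11 ± 0.24 (adjusted p 0.000313). Another gene named PAX2 (ENSDARG00000028148) was at -0.88 in the authors' table (DESeq2 adjusted p 0.00748). Of 31 hox genes 9 fell, or 12 adjusted over the list alone (camera adjusted p 0.000862; adjusted p = 0.0524 with an estimated correlation). HOXD3 was at -1.27 ± 0.24 (adjusted p 3.73e-05) and HOXB2 at -1.20 ± 0.31 (adjusted p 0.00365). In the DNA methylation list, which did not pass (camera adjusted p 0.233), 2 of 12 genes fell, DNMT1 by 0.59 ± 0.11 (adjusted p 5.23e-05) and tet3 by 0.85 ± 0.10 (adjusted p 5.33e-11). Apoptosis and stress genes had 5 rises and 2 falls among 18 (camera adjusted p 0.0844), with DDIT4, induced by stress, at 1.18 ± 0.13 (adjusted p 1.68e-11) and JUNB (ENSDARG00000104773) at -1.27 ± 0.33 (adjusted p 0.00346). Of 9 interferon genes 3 rose (camera adjusted p 0.0731), among them isg15 at 4.41 ± 0.45 (adjusted p 9.83e-13) and ifit8, with 22 counts against 0, at least 6.1-fold higher. The third, isg20, at 1.59 ± 0.42 (adjusted p 0.00481), was lost without H2A.Z-mCherry 5AzadC replicate 2 (0.286). These 3 lists kept their counts adjusted over the list alone. The other 13 lists had camera adjusted p values from 0.0731 to 0.947.

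In all, 2197 of 12293 genes changed in H2A.Z-mCherry, 1087 higher and 1110 lower, of which 736 changed by at least 1 on the log2 scale. The kinase gene brsk1a had 61 counts against 0, at least 16.9-fold higher, and rpz5 had 61 against 1, a ratio of 50.7 (95% interval 8.76 to 2040). At the other end IGFBP3 had 2 counts against 32, a ratio of 19.2 (95% interval 4.91 to 166), KCND2, a potassium channel gene, was at -3.48 ± 0.65 (adjusted p 3.08e-05) and foxg1b, a forebrain gene, at -2.87 ± 0.39 (adjusted p 2.14e-08). The total fell to 1400 without H2A.Z-mCherry 5AzadC replicate 2. Of the 75 genes named by the rule that passed, 74 had no overlap between groups, a share that the choice of these genes raises. Over all tested genes the share was 33.2%.

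**Figure D2:**
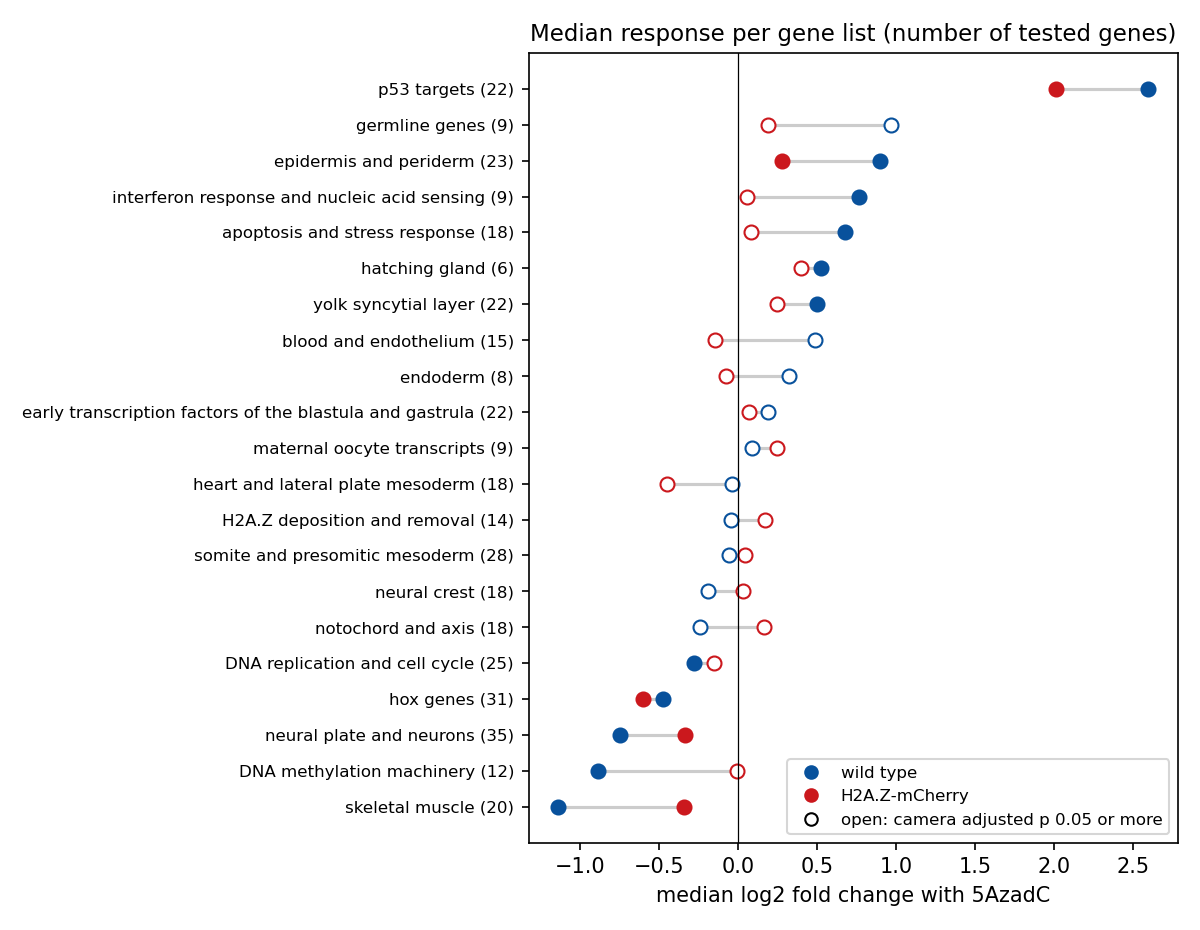
Median log2 fold change with 5AzadC (x axis) of the tested members of 21 gene lists (y axis, number tested in brackets) in wild type (blue) and H2A.Z-mCherry (red); open points did not pass camera at an adjusted p of 0.05, and points carry no error bars. The p53 targets have the highest median in both genotypes, 2.60 and 2.01, and skeletal muscle the lowest in wild type, -1.14.

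Set side by side, both genotypes shared much of the response. Of the called genes 547 rose in both genotypes and 614 fell in both, where independent lists would share 116 and 129, and 33 were called in opposite directions. Of 1551 genes called in wild type and not in H2A.Z-mCherry 221 passed the interaction test, as did 119 of the 1003 called in H2A.Z-mCherry and not in wild type. The orthogonal slope of the response in H2A.Z-mCherry on that in wild type was 0.713 over all tested genes (95% interval over genes 0.682 to 0.745), and 0.691 (0.657 to 0.726) over the 3748 genes called in either genotype. Simulated equal responses gave slopes from 0.977 to 1.003. Leaving out 1 library gave slopes from 0.584, without wild-type 5AzadC replicate 2, to 0.849, without H2A.Z-mCherry DMSO replicate 2. Of the genes called in wild type 85.2% had the smaller response in H2A.Z-mCherry, and of those called in H2A.Z-mCherry 63.9% had the smaller response in wild type, where simulated equal responses gave 57.8% to 60.5% and 57.5% to 60.3%. Simulated responses with a slope of 0.6 gave 92.9% to 94.6% and 20.8% to 24.0%, so the second share lay above both simulations and the first between them. Both simulations gave each gene the same or a proportional change in both genotypes. They held no gene that responded in 1 genotype alone, whereas 119 genes called only in H2A.Z-mCherry passed the interaction test. Their ranges of slopes and shares therefore hold for that simpler setting only.

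**Figure D3:**
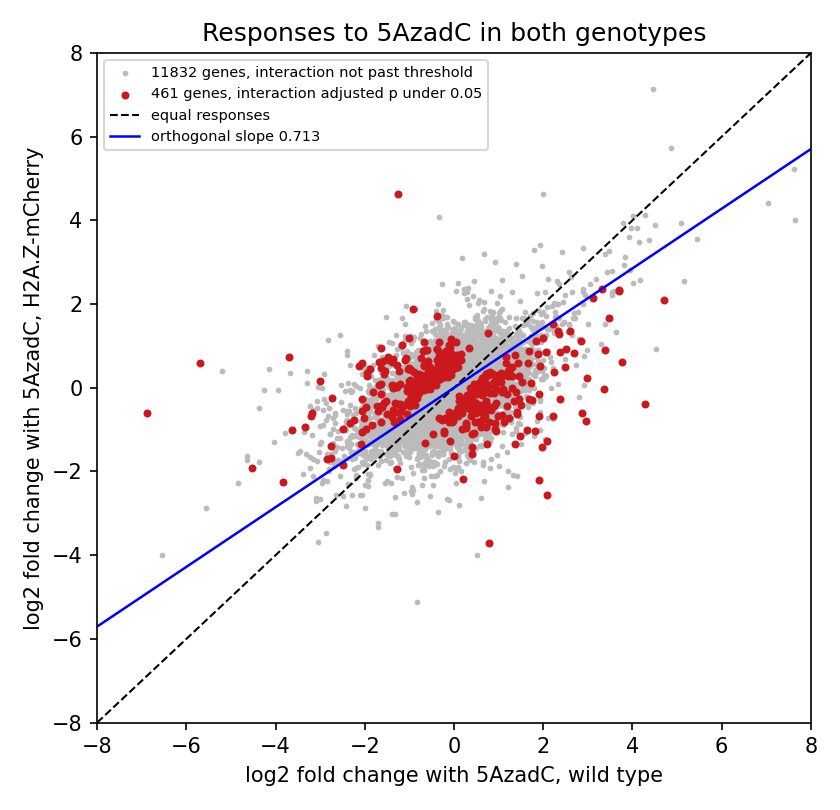
Log2 fold change with 5AzadC in wild type (x axis) against H2A.Z-mCherry (y axis) for 12293 tested genes; red points are the 461 genes past the interaction threshold, the dashed line marks equal responses and the blue line the orthogonal slope. The slope of 0.713 is flatter than the dashed line.

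The third comparison asked how H2A.Z-mCherry embryos differed from wild type without the drug. The H2A.Z genes did not pass: h2az2b was at 0.27 ± 0.09 (adjusted p 0.0746) and H2AZ2 at -0.08 ± 0.21 (adjusted p 0.906), although h2az2b passed adjusted over the list alone, where the count was 1 of 2. Transgene reads may add to either gene in H2A.Z-mCherry, in this and the later comparisons of genotypes. Epidermis and periderm genes went both ways, with 8 of 23 higher and 2 lower, or 11 and 2 adjusted over the list alone, and a median of 0.33 (camera adjusted p 0.00546; adjusted p = 0.45 with an estimated correlation). The tight junction gene cldnb was higher in H2A.Z-mCherry (1.12 ± 0.23, adjusted p 0.000591). The keratin gene krt4 was lower, at 1720 ± 217 CPM against 3506 ± 254 CPM (SD, n = 3; log2 fold change -1.03 ± 0.09, adjusted p 6.23e-11). Skeletal muscle genes were lower as a list, with a median of -0.23 and 1 of 20 above 0, although 2 passed singly, also 2 adjusted over the list alone (camera adjusted p 0.00546; adjusted p = 0.328 with an estimated correlation). The cardiac actin gene actc1b was at 33.7 ± 8.84 CPM against 100 ± 9.33 CPM (SD, n = 3; -1.55 ± 0.22, adjusted p 2.28e-07). The muscle list did not pass without H2A.Z-mCherry DMSO replicate 3 (0.0564). Among 9 maternal oocyte transcripts 2 were lower, also 2 adjusted over the list alone (camera adjusted p 0.044; adjusted p = 0.328 with an estimated correlation). That list did not pass without wild-type DMSO replicate 2 (0.172) or H2A.Z-mCherry DMSO replicate 1 (0.12). Its member CNOT6L, a subunit of the deadenylase that removes poly(A) tails, was at -2.42 ± 0.52 (adjusted p 0.000898).

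Outside these lists, the somite gene MEOX1 was higher in H2A.Z-mCherry with DMSO (2.26 ± 0.27, adjusted p 8.25e-10), as was JUNB (ENSDARG00000074378, 2.42 ± 0.48, adjusted p 0.00028), and the endothelial receptor gene tek was lower (-1.36 ± 0.32, adjusted p 0.00325). The genes named RRM2, for a subunit of ribonucleotide reductase, moved apart, ENSDARG00000020711 at -2.45 ± 0.43 (adjusted p 1.88e-05) and ENSDARG00000078069 at 0.82 ± 0.19 (adjusted p 0.00195). The 18 other lists tested had camera adjusted p values from 0.15 to 0.902; p53 targets had 2 of 22 lower (0.902) and apoptosis and stress genes 3 of 18 higher and 1 lower, or 4 and 3 adjusted over the list alone (0.726). In all 654 genes differed, 336 higher and 318 lower, 349 of them by at least 1 on the log2 scale, and the total was 423 without H2A.Z-mCherry DMSO replicate 3. The phosphodiesterase gene pde11al had 94.7 ± 27.1 CPM in wild type and 1.70 ± 0.07 CPM in H2A.Z-mCherry (SD, n = 3; -5.73 ± 0.35, adjusted p 1.18e-22). The bile acid receptor gene gpbar1 had 0 counts against 39, at least 11-fold lower, and ftr06 had 0 against 45, at least 12.7-fold lower. Higher in H2A.Z-mCherry were knl1, a kinetochore gene (4.37 ± 0.47, adjusted p 2.21e-11), bloc1s3 (4.03 ± 0.34, adjusted p 2.78e-15) and IGSF9B (4.51 ± 0.40, adjusted p 6.21e-15). Of the 48 genes named by the rule that passed, 47 had no overlap between groups, a share that the choice of these genes raises. Over all tested genes the share was 21.5%.

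The fourth comparison set the genotypes against each other under 5AzadC. The H2A.Z genes did not pass, h2az2b at 0.13 ± 0.09 (adjusted p 0.362) and H2AZ2 at 0.12 ± 0.20 (adjusted p 0.757). Genes of the drug's stress and damage response were lower in H2A.Z-mCherry. Of 22 p53 targets 9 were lower and 1 higher, also 9 and 1 adjusted over the list alone (camera adjusted p 6.91e-07; adjusted p = 0.0845 with an estimated correlation). The p53 inhibitor gene mdm2 was at 195 CPM against 446 CPM (-1.19 ± 0.13, adjusted p 1.64e-10). The gene cdkn1a, which stops the cell cycle, was at 42.4 ± 5.24 CPM against 94.4 ± 17.1 CPM (SD, n = 3; -1.15 ± 0.22, adjusted p 6.11e-05). Of 18 apoptosis and stress genes 9 were lower and 1 higher, or 10 and 1 adjusted over the list alone (camera adjusted p 6.91e-07; adjusted p = 0.0523 with an estimated correlation). JUNB (ENSDARG00000104773) was at -2.09 ± 0.32 (adjusted p 7.12e-07) and FOSL1 at -1.62 ± 0.34 (adjusted p 0.000349). Of 23 epidermis and periderm genes 8 were lower and 3 higher, or 10 and 3 adjusted over the list alone (camera adjusted p 0.000632; adjusted p = 0.269 with an estimated correlation). In that list krt4 was at -1.78 ± 0.09 (adjusted p 1.65e-17), cldnb at -0.94 ± 0.21 (adjusted p 0.000624) and anxa1b at 0.74 ± 0.17 (adjusted p 0.000679).

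Neural, DNA methylation and replication genes were higher in H2A.Z-mCherry than in wild type under 5AzadC. Of 35 neural plate and neuron genes 12 were higher and 1 lower, or 14 and 1 adjusted over the list alone (camera adjusted p 0.000307; adjusted p = 0.0523 with an estimated correlation). Its example DBX1, a spinal cord gene, was at 1.49 ± 0.44 (adjusted p 0.0117), a call lost without H2A.Z-mCherry 5AzadC replicate 2 (0.0976). Of 12 DNA methylation genes 4 were higher, or 6 adjusted over the list alone (camera adjusted p 0.000401; adjusted p = 0.0845 with an estimated correlation). Among them were UHRF1 (0.66 ± 0.12, adjusted p 2.8e-05), dnmt3bb.2 (0.50 ± 0.10, adjusted p 0.000229) and dnmt3ba (0.47 ± 0.09, adjusted p 0.000116). Of 25 DNA replication and cell cycle genes 9 were higher and 3 lower, or 12 and 3 adjusted over the list alone (camera adjusted p 0.0188; adjusted p = 0.226 with an estimated correlation). This list did not pass without wild-type 5AzadC replicate 1 (0.0755) or H2A.Z-mCherry 5AzadC replicate 1 (0.0841). CENPF, a centromere gene, was at 0.74 ± 0.15 (adjusted p 0.000195). The early transcription factors sox19b (1.34 ± 0.17, adjusted p 6.73e-09) and SOX3 (1.23 ± 0.19, adjusted p 8.14e-07), both genes of neural progenitors, were higher in a list that did not pass (camera adjusted p 0.356). The 15 lists that did not pass had adjusted p values from 0.127 to 0.899.

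In all 1918 genes differed under 5AzadC, 983 higher and 935 lower, 788 of them by at least 1 on the log2 scale. Again pde11al was lower, with 1 count against 526, a ratio of 715 (95% interval 128 to 28300), and PRKCQ, a protein kinase C gene, had 2 counts against 116, a ratio of 78.8 (21.3 to 658). At the other end knl1 had 182 counts against 2, a ratio of 67 (18.3 to 557), and POLQ, a DNA polymerase gene of end joining, had 46 against 0, at least 11.3-fold higher. Of the 654 genes that differed with DMSO 344 also differed in the same direction under 5AzadC, 173 higher and 171 lower, where independent lists would share 26.9 and 24.2, and 37 differed in opposite directions. Of the 75 genes named by the rule that passed, 71 had no overlap between groups, a share that the choice of these genes raises. Over all tested genes the share was 30.4%.

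The fifth comparison tested whether the response to 5AzadC differed between genotypes. A higher or lower response here refers to the log2 fold change with its sign, not to its size. For the H2A.Z genes the interaction did not pass, h2az2b at -0.14 ± 0.13 (adjusted p 0.657) and H2AZ2 at 0.20 ± 0.29 (adjusted p 0.803). Epidermis and periderm genes responded less in H2A.Z-mCherry, with 7 of 23 past the threshold, or 8 lower and 1 higher adjusted over the list alone (camera adjusted p 4.83e-10; adjusted p = 0.0592 with an estimated correlation). The keratin gene krt17 rose from 273 ± 33.5 to 672 ± 55.8 CPM in wild type and stood at 441 ± 81.0 and 441 ± 68.8 CPM in H2A.Z-mCherry (SD, n = 3; interaction -1.30 ± 0.16, adjusted p 5.78e-07). For cldnb the response was 1.91 ± 0.22 in wild type and -0.15 ± 0.22 in H2A.Z-mCherry (interaction -2.06 ± 0.31, adjusted p 5.17e-06). In the p53 list 5 of 22 genes responded less, or 7 with 2 responding more adjusted over the list alone (camera adjusted p 6.91e-05; adjusted p = 0.0803 with an estimated correlation). The gene mdm2 rose by 3.71 ± 0.16 in wild type and by 2.35 ± 0.16 in H2A.Z-mCherry (interaction -1.36 ± 0.24, adjusted p 7.11e-05). In the stress list 5 of 18 passed, or 6 lower and 1 higher adjusted over the list alone (camera adjusted p 2.35e-07; adjusted p = 0.0526 with an estimated correlation). TXNIP was at -1.20 ± 0.14 (ENSDARG00000036107, adjusted p 8.99e-09). In the blood and endothelium list 4 of 15 had the lower response, also 4 adjusted over the list alone (camera adjusted p 0.0044; adjusted p = 0.0526 with an estimated correlation). CEBPB was at -1.73 ± 0.40 (adjusted p 0.00441).

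Several lists that fell in wild type fell less in H2A.Z-mCherry, which gave a higher signed response there. The medians in wild type and H2A.Z-mCherry were -0.89 and -0.0038 for DNA methylation and -0.28 and -0.15 for replication and cell cycle. They were -1.14 and -0.34 for skeletal muscle and -0.74 and -0.33 for neural plate and neurons. Of 12 DNA methylation genes 2 passed, also 2 adjusted over the list alone (camera adjusted p 6.61e-05; adjusted p = 0.0526 with an estimated correlation). UHRF1 went from 267 to 129 CPM in wild type and from 203 to 204 CPM in H2A.Z-mCherry (interaction 1.06 ± 0.17, adjusted p 8.03e-06), and dnmt3ba was at 0.57 ± 0.13 (adjusted p 0.00409). Of 25 replication and cell cycle genes 5 had the higher and 1 the lower response, or 11 and 2 adjusted over the list alone (camera adjusted p 0.00125; adjusted p = 0.0738 with an estimated correlation). MCM2 was at 0.83 ± 0.14 (adjusted p 5.29e-05). Of 20 skeletal muscle genes 4 passed, or 5 adjusted over the list alone (camera adjusted p 5.29e-05; adjusted p = 0.0526 with an estimated correlation). TTN was at 0.53 ± 0.11 (ENSDARG00000028213, adjusted p 0.00155). Of 35 neural plate and neuron genes 2 passed, or 4 adjusted over the list alone (camera adjusted p 0.0044; adjusted p = 0.0681 with an estimated correlation). The response of sox19a was -0.61 ± 0.12 in wild type and 0.34 ± 0.12 in H2A.Z-mCherry (interaction 0.95 ± 0.18, adjusted p 0.000145). In the notochord and axis list, which did not pass in wild type, the camera adjusted p was 0.0063 (adjusted p = 0.0765 with an estimated correlation). Of its 18 genes 5 had a higher response adjusted over the list alone but did not pass over all genes. The other 12 lists had camera adjusted p values from 0.168 to 0.958. In all 461 genes passed, 233 with the higher and 228 with the lower response in H2A.Z-mCherry. The prostaglandin synthase gene PTGS2 (ENSDARG00000010276) went from 18.9 ± 8.54 to 74.2 ± 12.7 CPM in wild type (SD, n = 3). In H2A.Z-mCherry it went from 60.4 ± 17.8 to 22.3 ± 1.18 CPM (SD, n = 3; interaction -3.39 ± 0.36, adjusted p 1.41e-10).

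**Figure D4:**
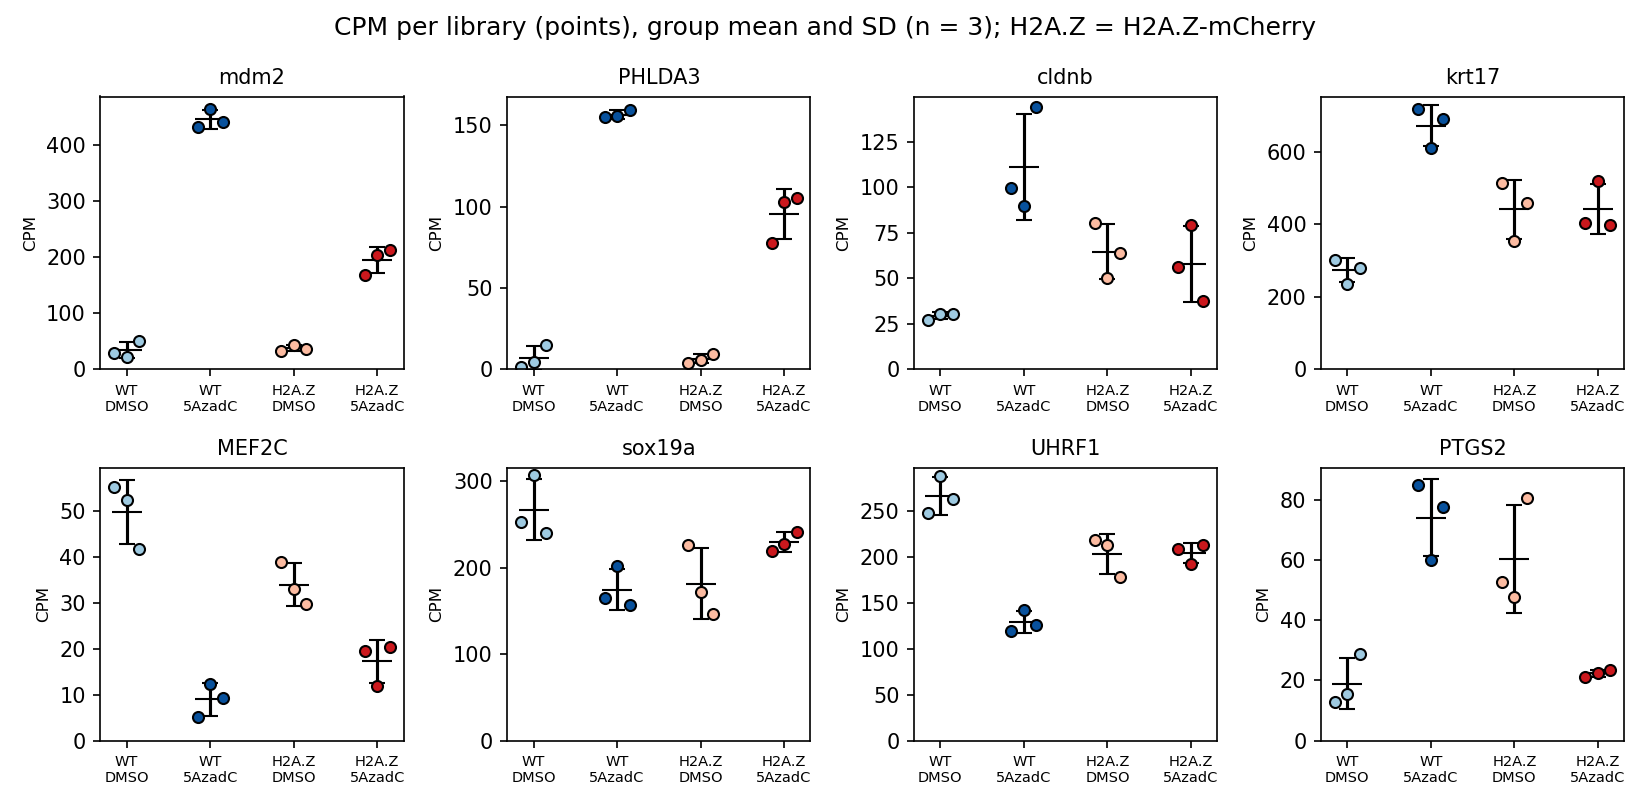
CPM (y axis, from 0) of 8 genes in the 4 groups (x axis); points are single libraries, the horizontal bar is the group mean and the error bar its SD (n = 3). The p53 targets mdm2 and PHLDA3 are higher with 5AzadC in both genotypes, while krt17 and UHRF1 change in wild type and stay at 441 and 441 CPM and at 203 and 204 CPM in H2A.Z-mCherry.

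The authors' deposited tables gave 2126 genes past an adjusted p of 0.05 for 5AzadC in wild type, 1000 higher and 1126 lower, and 1681 in H2A.Z-mCherry, 782 higher and 899 lower. Of these 2078 and 1673 were also called here in the same direction. Across the 12293 tested genes, which are not independent replicates, the log2 fold changes of both sources had a Pearson correlation of 0.999 in each genotype.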

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

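The tests of the choice of genes, of a common scaling and of equal depth were chosen after the result was seen; the counts over other splits of the libraries were planned. Each value in this part was singled out because a test of the interaction found that the response to 5AzadC differed between H2A.Z-mCherry and wild type.

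The slope of the response to 5AzadC in H2A.Z-mCherry on that in wild type was below 1, and 461 genes passed the interaction test, 321 of them with the smaller response in H2A.Z-mCherry. Choosing genes by 1 genotype favours a larger response there. Of genes called in wild type 85.2% were smaller in H2A.Z-mCherry, and of those called in H2A.Z-mCherry 63.9% were smaller in wild type. The second share lay above simulated equal responses (57.5% to 60.3%) and a simulated slope of 0.6 (20.8% to 24.0%), so the response was not smaller throughout. Those simulations held no gene that responded in 1 genotype alone. Choosing genes by 1 genotype as the whole cause is argued against, in these libraries, by the 3669 genes called on the mean response of both genotypes. Of these 61.4% (95% interval over genes 59.8% to 63.0%) were smaller in H2A.Z-mCherry. Genes share the same 12 libraries, so this interval does not cover the spread between libraries. The share was not computed with 1 library left out. Unequal depth is argued against by thinning all libraries to the lowest total, where the highest slope of 10 draws was 0.735, and a single scaling of every response by 140 genes past the threshold with the larger response in H2A.Z-mCherry, where the false discovery rate allows 23.1. What remains may be biological, as a hypothesis found and tested on the same data, while the line's background and clutch, which the design does not separate from the transgene, stay open and untested, and leaving out 1 library moved the slope between 0.584 (wild-type 5AzadC replicate 2) and 0.849 (H2A.Z-mCherry DMSO replicate 2).

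Of 100 splits of the libraries drawn from 200 that exchange genotype labels, 4 gave at least 461 genes, the real one included, and the highest other split gave 688. The 3 splits above the real value exchanged the genotype of all 5AzadC libraries and kept that of 2 of 3 DMSO libraries per genotype, so they put the genotype difference shared by both treatments into the interaction. Since exchanged labels carry this difference, the splits do not settle whether chance can be excluded.

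Of the gene lists, 9 passed the interaction test with camera. The adjusted p was 4.83e-10 for epidermis and periderm, 2.35e-07 for apoptosis and stress response and 6.91e-05 for p53 targets, and it was 0.0044 for blood and endothelium, each with a median below 0. It was 5.29e-05 for skeletal muscle, 6.61e-05 for DNA methylation, 0.00125 for DNA replication and cell cycle, 0.0044 for neural plate and neurons and 0.0063 for notochord and axis, each with a median above 0. With an estimated correlation each of the 9 lost its call, with adjusted p values from 0.0526 to 0.0803.

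Among named genes whose interaction passed without any 1 library, the log2 difference was 2.65 for HMGA2, 1.06 for UHRF1, 0.95 for sox19a, 0.83 for MCM2, 0.76 for TFAP2C, 0.59 for MCM3, 0.57 for dnmt3ba and 0.53 for TTN (ENSDARG00000028213). Below 0 were JUNB (-4.64 for ENSDARG00000074378 and -3.36 for ENSDARG00000104773), fosaa (-4.48), irg1l (-3.76), PTGS2 (-3.39), ets2 (-2.85), FOSL1 (-2.65), cldnb (-2.06), CEBPB (-1.73), cdkn1a (-1.73), TP53INP1 (-1.37), mdm2 (-1.36), krt17 (-1.30), TXNIP (-1.20), krt92 (-0.93), cyt1l (-0.91) and apoa1b (-0.68).

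For 24 other named genes the call was lost when 1 library was left out, and the adjusted p given is the highest of these fits; each call was ended by 1 to 9 of the 12 libraries. Without wild-type 5AzadC replicate 1 it was 0.0626 for CSRP3 (log2 difference 6.29), 0.117 for pop5 (4.42), 0.102 for BRD2 (-0.52), 0.0694 for MCM5 (0.64), 0.162 for sox19b (0.80), 0.161 for MEF2C (1.51), 0.129 for NKX6-1 (1.74), 0.0569 for HOXC6 (-1.17), 0.163 for etsrp (-1.60) and 0.121 for npas4l (-1.01). Without wild-type 5AzadC replicate 3 it was 0.0954 for actc1b (1.23). Among wild-type DMSO libraries it was 0.142 for CCNA2 (0.71) and 0.194 for SOX3 (0.83) without replicate 1, 0.0727 for SOX7 (-1.96) without replicate 2, and 0.112 for PPP6R2 (2.80) and 0.191 for MEOX1 (-1.22) without replicate 3. Without H2A.Z-mCherry DMSO replicate 1 it was 0.141 for SLC27A1 (-4.68) and 0.0655 for stard14 (-4.12), and without replicate 2 it was 0.0982 for SESN1 (-0.94). Among H2A.Z-mCherry 5AzadC libraries it was 0.103 for LDB2 (2.65), 0.0923 for foxd1 (2.62) and 0.087 for TTN (ENSDARG00000000563, 0.46) without replicate 1, and 0.148 for HPSE2 (3.17) and 0.19 for msgn1 (0.74) without replicate 3. DESeq2 also ended the calls of SOX3 (0.0935), MEOX1 (0.0678), msgn1 (0.064) and MEF2C (0.052), the replicate block those of HPSE2 (0.0587), SOX3 (0.0539) and etsrp (0.0508), and DESeq2 size factors that of SOX3 (0.0529). The fitted values of CSRP3, pop5 and SLC27A1 depend on the prior count, since 1 group held 0, 1 and 2 counts.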

How the results depend on the processing

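Thinning of the libraries and a filter of 20 CPM in 3 libraries were chosen after seeing the data and the other alternatives were planned; the test of genes on the long arm of chromosome 4 was not run. No called named gene changed direction with DESeq2 (353 of 385 results compared), its size factors, upper quartile factors, the replicate block or 1 library left out, which were the alternatives run for single genes, and no called list did with fry for 1 direction, the block or 1 library left out. Outside the interaction most called named genes had groups that did not overlap, so a change of direction was hardly possible for them. In the order 5AzadC in wild type, 5AzadC in H2A.Z-mCherry, genotype in DMSO, genotype in 5AzadC and interaction, an adjusted p under 0.01 left 1751, 1278, 341, 1065 and 189 genes, and an absolute log2 fold change of at least 1 left 1213, 736, 349, 788 and 191, since both are stricter thresholds. DESeq2 called 2145, 1688, 467, 1392 and 365, of which 2119, 1680, 430, 1337 and 347 were also called by edgeR in the same direction. Other scalings and filters and the replicate block left these counts within 1.5 times, and the largest shift of the median over all genes was -0.0254 (upper quartile factors, wild type). Leaving out 1 library gave 2156 to 2402, 1400 to 1948, 423 to 560, 1379 to 1751 and 312 to 569 genes, with fewer libraries in each; 1400 was without H2A.Z-mCherry 5AzadC replicate 2 and 423 without H2A.Z-mCherry DMSO replicate 3.

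The slope of the responses was 0.601 with a filter of 1 CPM in 3 libraries, which is looser than filterByExpr and adds 7281 genes with few counts; over the 12293 genes of the main filter that fit gave 0.713. It was 0.725 with the filter of 20 CPM, which left 7907 genes, and 0.584 to 0.849 with 1 library left out; leaving out a library makes the response of its genotype noisier. Of the list tests, those with an estimated correlation passed in 1 list for H2A.Z-mCherry and in 0, 0 and 0 for genotype in DMSO, genotype in 5AzadC and the interaction, where 3, 6 and 9 passed with the preset value of camera. Unadjusted, p with an estimated correlation was under 0.05 in 3, 4 and 9 lists. For genotype in DMSO these were not the same lists as with the preset value. Early transcription factors (0.0468) were among them without having passed before (camera adjusted p 0.15), and epidermis and periderm was at 0.136. Fry passed in 9, 6 and 15 lists for H2A.Z-mCherry, genotype in DMSO and genotype in 5AzadC, and its test for change in either direction in 20, 17, 12, 19 and 16 over the 5 contrasts, which asks another question. With 1 library left out 10 to 12, 5 to 9, 2 to 4, 5 to 6 and 9 to 9 lists passed. Of 34 list calls 24 were lost with an estimated correlation and 1 with fry, and of 336 calls of named genes 127 were lost without at least 1 library; 57 of 310 were lost with DESeq2. Replicate numbers did not pair the libraries (r from -0.026 to 0.024 over 18 pairs). Totals of 1142051 to 1904063 counts limit what can be seen in genes with few counts.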

Other observations

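The gene families in the first paragraphs and FOS were chosen after their values were seen, as were the tests of chance calls, of the lines' background, of a delay and of a few abundant genes; the counts over splits of the libraries were planned.

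Some gene families outside the lists are given as counts of genes that passed singly, with no test of the family, since they were picked for their values; each median kept its sign under each scaling tried. Of 70 ribosomal protein genes 56 rose in wild type and 54 in H2A.Z-mCherry, with medians of 0.56 and 0.37. Of 35 proteasome genes 16 rose in wild type and 17 rose and 1 fell in H2A.Z-mCherry, with medians of 0.48 and 0.58, and of 55 translation initiation factor genes 17 and 23 rose, with medians of 0.22 and 0.36. Of 35 collagens 21 fell in wild type and 13 in H2A.Z-mCherry, with medians of -1.01 and -0.73. Of 13 plexins, receptors of semaphorins, 8 fell in each genotype, with medians of -0.60 and -0.66. Of 21 Eph receptors and ephrins 12 fell in each genotype and 1 rose in wild type. Protocadherins had 8 falls among 21 in wild type and 6 falls and 1 rise in H2A.Z-mCherry, and semaphorins had 7 and 3 falls among 20.

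PTGS2 and ets2, which were picked for this after their values were seen, were higher in wild type with 5AzadC and in H2A.Z-mCherry with DMSO than in the other groups. PTGS2 (ENSDARG00000010276) had 18.9, 74.2, 60.4 and 22.3 CPM in wild type with DMSO, wild type with 5AzadC, H2A.Z-mCherry with DMSO and H2A.Z-mCherry with 5AzadC, and ets2, a transcription factor gene, had 10.7, 38.5, 33.2 and 15.6 CPM in the same order. FOS had another profile. For FOS, an AP-1 gene, the log2 fold change with 5AzadC was 3.77 ± 0.30 in wild type (adjusted p 7.45e-18) and 0.61 ± 0.25 in H2A.Z-mCherry (adjusted p 0.0834), and the interaction was -3.16 ± 0.40 (adjusted p 4.45e-08). Between H2A.Z-mCherry and wild type it was 2.16 ± 0.33 with DMSO (adjusted p 9.87e-07) and -0.998 ± 0.23 with 5AzadC (adjusted p 0.000942).

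Of the genotype differences called with DMSO 52.6% were called again with 5AzadC in the same direction, 344 genes in all. Chance calls are argued against, since independent calls would share 51.1 genes. A background that differs between the lines might group such genes along chromosomes. Only 62.8% of the 344 could be placed on the available annotation, of another build, where 80% was needed, so this was not decided. A clutch difference need not group genes, so this check could not have covered it. Background, clutch and transgene could each give the pattern and cannot be told apart, since each genotype is a single line. The share was 77.3% for an absolute log2 fold change of at least 2 with DMSO, with 3 genes called in the opposite direction, and 40.7% for one under 1, with 25.

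In wild type, epidermis genes were higher and muscle genes lower with 5AzadC. A few genes taking most of the counts are argued against, since the share of the 20 most counted genes went from 17.9% to 20.2%, which uncorrected would move all other genes by at most 0.0494 on the log2 scale, and the lists moved in opposite directions. A delay of the whole embryo might lower muscle genes, and it would lower hatching gland genes too; their median was 0.53, with 4 of 6 higher, but that list had an adjusted p = 0.24 with an estimated correlation and lost its call without wild-type DMSO replicate 1 (0.09), wild-type 5AzadC replicate 1 (0.0663) or replicate 2 (0.0703). A delay and a change of tissue therefore cannot be told apart here.

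For the other contrasts, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split, 1 of 10 in each, gave 2745 genes for 5AzadC in wild type with 0 as the highest other, 2197 for 5AzadC in H2A.Z-mCherry with 1, 654 for genotype in DMSO with 2 and 1918 for genotype in 5AzadC with 0.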
